A study of Arabidopsis thaliana with 6 samples.

How the data were processed

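Transcript levels were measured on Affymetrix ATH1 arrays, a single-colour format on which biotin-labelled cRNA from 1 sample is hybridised to short oligonucleotide probe sets. The samples were Arabidopsis thaliana Columbia pollen at 3 stages, with 2 arrays per stage and 6 arrays in all. Mature pollen was collected dry from open flowers by vacuum. Hydrated pollen and pollen tubes were released from flowers by vigorous shaking in a sucrose and salt medium, spun down, and kept as a thin liquid film at 25 °C, for 45 min in the hydrated samples and for 4 h in the tube samples. Tubes had reached about 150 µm and were retained on a 50 µm mesh. Plants were 50 days old, and 8 µg of RNA and 20 µg of cRNA went into each array, per the labels' protocols. The series' design text calls the replicates biological, and no shared origin of arrays with the same replicate number is given in the sources used here.

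The deposited values are linear signal intensity, 1 value per probe set and array. GCOS 1.0 and MAS5 are named in the submitters' processing notes. The mean of each array's values without the lowest and highest 2% lay between 99.88 and 99.9 on every array, which is what scaling each array separately to a common target gives. Whether any further step was applied is not given in the sources used here. Detection calls were not used here, so a probe set was treated as above background only by its rank on the array.

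The table held 22810 probe sets. The 64 control probe sets were left out of the tests. Values below 0.1 were set to 0.1, which concerned 1 value of 0 on the second tube array, and log2 was taken. A probe set was tested if it lay above its array's 60th percentile on at least 2 of the 6 arrays, whichever stage they belonged to, and 11412 probe sets passed. A fold change against a stage in which neither array lay above that percentile is a bound: the mean of the bright stage over the mean of the percentile values, or over the probe set's own value where that was higher, written as "at least".

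Names came from the platform annotation, updated through a reference gene table of the TAIR10.1 assembly. Of the probe sets, 13513 were paired with 1 gene and 503 with several, and 8730 that are not controls were unnamed here. The single-gene probe sets stood for 13356 genes, and 13436 of these probe sets had their gene in the reference table. Among those tested, 6511 carried 1 gene and 4901 carried several or were unnamed here. Counts of changed probe sets include the unnamed ones, and a gene absent from a list below may be on the array without a name here. No genome build is named for the array, so coordinates are not given. The reference table used here holds no gene descriptions, so families planned by description were left out, and what a gene is known to do is given as background.

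The stages were compared with limma 3.58.1 in R 4.3.3. One fit held a mean for each of the 3 stages over all 6 arrays, so that the comparisons shared 1 estimate of the spread, with 3 residual degrees of freedom. The moderated test with an intensity trend was two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 11412 probe sets within each comparison, and an adjusted p under 0.05 was called a change. The comparisons were hydrated against mature pollen, tubes against hydrated pollen, and tubes against mature pollen, which is the sum of the other two. An F test across the stages was run as well. With 2 arrays per stage, the number of arrays limits the precision.

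Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene, the brightest over all arrays. Lists with at least 5 tested members entered, adjusted over those lists within a comparison. Camera with an estimated correlation and limma's fry were run beside it. Fry asks whether the members of a list move on balance one way, without setting them against other genes. The 15 lists fixed beforehand covered tip growth signalling, calcium and ion transport, actin cytoskeleton, cell wall, sugar transport, vesicle traffic, pollen transcription factors, sperm cell, heat shock, dehydration and late embryogenesis abundant (LEA) proteins, early touch and wound response, and, as markers of other tissues, photosynthesis, floral organs, epidermis and tapetum. Of these, 5 had enough tested members. They were tip growth signalling (10 of 34 listed), actin (8 of 25), cell wall (7 of 31), transcription factors (8 of 14) and heat shock (6 of 25). Most other members of the fixed lists were unnamed here, so a list that is not called says nothing of them. A further 23 lists were drawn up after the probe annotation had been seen and before any comparison was computed, and 19 of them had enough members. They were cytosolic ribosomal proteins, pectin methylesterases, polygalacturonases and pectate lyases, heat shock proteins of the HSP20, HSP70 and HSP90 families, plastid-encoded genes, SWEET sugar carriers, RALF-like peptides, expansins, xyloglucan endotransglucosylases, trichome birefringence-like proteins, CHX cation exchangers, glutamate receptor-like channels, MADS-box factors, UDP-glycosyltransferases, serine carboxypeptidase-like proteins, VPS, SEC and EXO vesicle proteins, autophagy proteins, ubiquitin-pathway enzymes, tetraspanins, IQD proteins, tau glutathione transferases, genes with CYP symbols, taken as cytochromes P450 although CYP71 is a cyclophilin, and beta-glucosidases.

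Genes named below follow a fixed rule. For each step, among single-gene probe sets past the threshold with the arrays of the stages not overlapping, the 6 highest and 6 lowest log2 changes were taken among those above the percentile on all 4 arrays. The 4 highest bounds among rises from background and the 4 among falls to background were added. For tubes against mature pollen 3 and 2 were taken in their place. Up to 3 changed members of each list with the largest change, or the brightest member where none changed, completed the names. Other members of short lists, genes changed at both steps and genes whose steps differed were named after their values had been seen. The stages, tests, thresholds, fixed lists, naming rule and most alternatives were chosen before the data were examined.

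The replicate numbers of the labels were checked for pairing by correlating, between stages, the difference of the second array from the first. Over the tested probe sets the correlations, across probe sets, were 0.174 for mature and hydrated pollen, 0.221 for mature pollen and tubes, and 0.185 for hydrated pollen and tubes. Over the 2468 probe sets with a mean signal above 200 they were 0.739, 0.687 and 0.775. Only 2 numbers exist, with 1 array of each stage per number. All of these correlations exceeded 0.1, the level set here for pairing. The fit with the replicate number as a block was planned as an alternative. Stage means alone stayed the main fit because the labels give a number and no shared origin. A probe set said below not to pass in the main fit may therefore pass with the block. Because the control probe sets split by number as well, the number was treated as a technical batch seen in the data, and blocked values, and changes within each number, are given with the results they alter. The block leaves 2 residual degrees of freedom.

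The fit was tested on simulated data with the spread of these arrays and 200 of the 11412 probe sets changed in each of 20 draws. For hydrated against mature pollen it recovered 0% of changes of 1 on the log2 scale, 4.67% of changes of 2 and 40% of changes of 4. For tubes against hydrated pollen it recovered 0%, 5.33% and 37.9%, and for tubes against mature pollen 0%, 5.71% and 37.4%. False calls were 0.172%, 0.181% and 0.337% of all calls. With the replicate block, recovery at a change of 2 was 40.8%, 40.8% and 41.3%, and false calls were 8.33%, 8.08% and 7.77% of all calls. A simulated list of 8 members moved by 1 was called in 20 of 20 draws by camera with the preset correlation and in 19 of 20 with an estimated one, and an unmoved list in 0 of 20 by either. The simulated probe sets varied independently of each other, so these draws cannot show how either version behaves where list members are correlated. For the heat shock list at hydration the estimated correlation was 0.284.

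Alternatives changed 1 choice at a time: the filter (none, the 75th percentile, or the mean signal), the scaling (quantile normalization, or a common 75th percentile), a floor at a common 60th percentile, an offset of 32 before log2, limma without the trend, only the 4 arrays compared, the replicate block, an added requirement of at least 2-fold, an adjusted p under 0.01, 1 probe set per gene, and leaving out each array in turn. Where an array is left out, the remaining array of its stage is assumed to vary like the other stages.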

Results

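Transcripts of dry mature pollen, of pollen hydrated for 45 min in medium and of pollen tubes grown for 4 h were compared on 2 arrays per stage, following the series' stated interest in the changes that accompany germination and tube growth. Array medians ranged from 14 on the second tube array to 24.4 on the first mature array, and the highest signals from 26820.4 to 43798.8, in arbitrary units. The 60th percentile, used here as the limit of background, lay between 19.7 and 34.1. Replicate arrays of a stage had a mean Pearson coefficient of 0.936 across the probe sets with a mean signal above 200, and arrays of different stages 0.841 when they shared a replicate number and 0.794 when they did not. Between replicate numbers, the coefficient was 0.926 within mature pollen and 0.942 within hydrated pollen, and 0.884 and 0.881 from mature to hydrated pollen. Within a replicate number, mature and hydrated arrays reached 0.935 and 0.927, as close as the replicates of a stage. Genes are not independent replicates in these coefficients. The median absolute log2 difference between the 2 replicates of a stage was 0.711 in mature pollen, 0.612 in hydrated pollen and 0.655 in tubes over the tested probe sets. Below, levels are mean signal ± SD (n = 2 arrays), changes are log2 values ± SE, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. In every gene given as risen or fallen, both arrays of one stage lay beyond both arrays of the other. The direction was therefore the same within each replicate number. The naming rule asked for this in the genes with the highest and lowest changes and bounds, so it adds no support to them. Of all 11412 tested probe sets, 3839 were apart in this way in hydrated against mature pollen. The counts were 4917 in tubes against hydrated pollen and 5249 in tubes against mature pollen.

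The first comparison asked what changes between dry mature pollen and hydrated pollen. Mature pollen was collected dry by vacuum, and hydrated pollen was shaken from flowers in medium and spun down. For every change at this step, hydration therefore cannot be told apart from collection and handling. Rises outnumbered falls, and heat shock genes were prominent among the named rises. AT1G53540, a class I small heat shock protein (HSP17.6C), went from 44.95 ± 20.01 to 1671.2 ± 925.6 (5.17 ± 0.47, adjusted p = 0.000677), with 5.30 within replicate number 1 and 5.05 within number 2. AT1G54050, a class III small heat shock protein, rose at least 37.7-fold from background (adjusted p = 0.00103), and Hsp70-2, a cytosolic HSP70 chaperone, at least 13-fold (adjusted p = 0.000197). The highest bound belonged to AT1G74450, which rose at least 65.0-fold to 2095.6 ± 1248 (adjusted p = 0.00014). AT5G04760, a MYB-related transcription factor, rose at least 18.4-fold (adjusted p = 0.00244). AT1G76640, a calmodulin-like protein, rose from 234.25 ± 62.3 to 5326.6 ± 1737 (4.49 ± 0.37, adjusted p = 0.000419). AT3G19690, a secreted protein of the CAP family to which pathogenesis-related protein PR-1 belongs, rose by 3.45, AT5G10695 by 3.32, AT5G37230 by 3.22 and AT3G19240 by 3.14, with adjusted p between 0.00103 and 0.00507. The probe set of AT5G37230 may take signal from related genes.

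Few falls passed in hydrated pollen with stage means alone, 6 against 128 with the replicate number as a block. The named ones concerned abundant transcripts of mature pollen. AT2G19000 went from 16282 ± 5040 to 2812.6 ± 1963 (-2.70 ± 0.47, adjusted p = 0.0328), AT4G18395 from 9990.3 ± 1018 to 2198.1 ± 1028 (-2.26 ± 0.36, adjusted p = 0.0175) and AT1G63060 from 3606.3 ± 40.45 to 697.5 ± 162.9 (-2.39 ± 0.31, adjusted p = 0.00433). AT1G35490, a bZIP transcription factor, fell by 2.77 ± 0.51 (adjusted p = 0.0453), and its change differed between the replicate numbers, at -4.09 in number 1 and -1.45 in number 2.

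In all, 66 of the 11412 tested probe sets changed, 60 upward and 6 downward, and each changed by at least 2-fold. Of these, 28 rises and 4 falls carried 1 gene name. With the replicate number as a block 421 changed, 293 upward and 128 downward, and all 66 were among them. Limma without the intensity trend called 0, with 731 at an unadjusted p under 0.05, and a floor at the 60th percentile gave 27 rises and 0 falls. The count was 29 without hydrated array 2, 38 without hydrated array 1, and 43 without either tube array.

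Among the fixed lists, heat shock had 6 tested members, of which 3 rose, 0 fell and 3 did not pass. Adjusted over the list alone, 5 rose, as they did with the replicate block. The risen members were AT1G53540, Hsp70-2 and AT5G48570, the FKBP-type immunophilin ROF2, which went from 62.2 ± 63.64 to 857.9 ± 58.55 (4.32 ± 0.66, adjusted p = 0.0149). On the second mature array AT5G48570 read 17.2, below the 60th percentile of 25.1. Its change was 3.07 within replicate number 1 and 5.57 within number 2. ATHSP22.0 (adjusted p = 0.0585) and AT5G51440 (adjusted p = 0.225), both at background in mature pollen, and AT3G09440 (0.47, adjusted p = 0.966) did not pass. The median of the list was 3.66, or 2.95 with members rising from background set at their bound, and camera called it (adjusted p = 6.21e-16), whereas it was not called at adjusted p = 0.0601 with an estimated correlation. Fry gave an adjusted p of 0.0116.

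**Figure D1:**
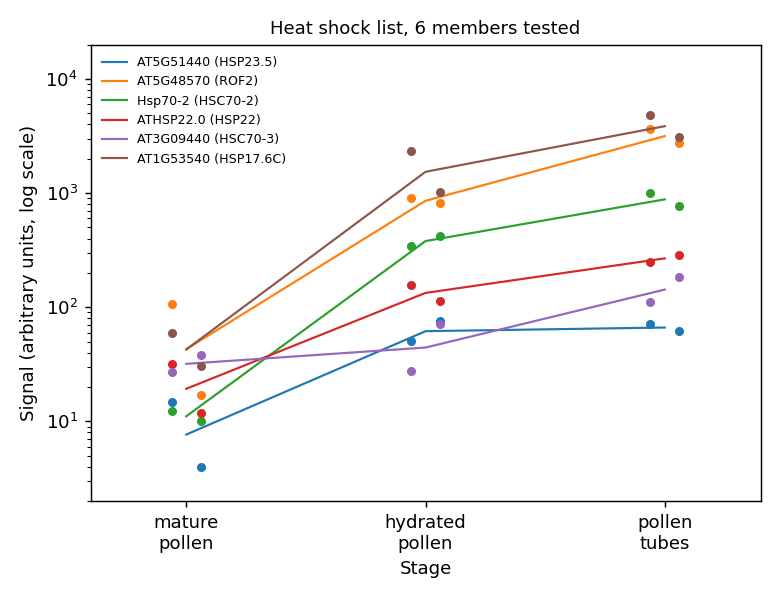
Signal of the 6 tested members of the heat shock list on each array (points, log scale, arbitrary units) by stage, with lines through the stage means of log2 signal. AT1G53540 lies between 30.8 and 59.1 in mature pollen and between 1016.7 and 2325.7 in hydrated pollen.

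Pollen transcription factors, mostly MADS-box and bZIP genes, had 8 tested members, of which 0 rose, 0 fell and 8 did not pass in limma. Adjusted over the list alone none passed either, and 2 fell with the replicate block. AGL18, a MADS-box factor and the brightest of them, changed by -0.76 (adjusted p = 0.66, and 0.0183 with the block). The median was -0.68 and camera called the list downward (adjusted p = 0.0261), which was lost at adjusted p = 0.271 with an estimated correlation, at 0.0816 with the arrays scaled to a common 75th percentile, at 0.195 with a floor at the 60th percentile and at 0.0888 without a filter. It was also lost without mature array 2 (adjusted p = 0.626) and without hydrated array 1 (adjusted p = 0.194).

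The cell wall list (7 tested, median -0.06, camera adjusted p = 0.471), the actin list (8 tested, median -0.13, adjusted p = 0.471) and the tip growth signalling list (10 tested, median -0.13, adjusted p = 0.63) were not called, and none of their members passed. Without mature array 1 the cell wall list was called downward (adjusted p = 0.0357). With the block, 2 cell wall, 1 actin and 1 tip growth member fell. The brightest members, the polygalacturonase AT3G07820 at -0.06 ± 0.36, the LIM-domain actin-binding protein PLIM2a at -0.11 ± 0.31 and the leucine-rich extensin AT1G49490 at 0.16 ± 0.53, differed by less than the spread between replicates. Early touch and wound genes had 3 tested members of 36 listed and 0 passed, while 2 rose adjusted over the list alone and 2 with the block. These were the U-box ubiquitin ligases PUB23 (adjusted p = 0.0571) and PUB22 (adjusted p = 0.0549), both at background in mature pollen, with bounds of at least 4.81-fold and 2.12-fold. Without a filter this list was large enough for camera and was called upward here (adjusted p = 0.000691), at the tube step (0.0484) and in tubes against mature pollen (0.000671). None passed among the few tested members of the lists that follow. Tested were 4 of 21 listed for sugar transport (AtVEX1 -0.19), 4 of 18 for vesicle traffic (the phosphoinositide kinase PIPK11 -0.01) and 2 of 37 for calcium and ion transport (ATGLR1.2 -0.26). Dehydration and LEA had 2 of 19 (LEA4-5 -1.25), and sperm cell 1 of 12, the histone variant MGH3 (-0.09).

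The named markers of other tissues stayed low on these arrays. Of the lists for photosynthesis, floral organs, tapetum and epidermis, 9 genes were named on the array. These were 4 of 27 listed for photosynthesis, 2 of 11 for floral organs and 3 of 17 for tapetum. RCA, SWEET9 and the tapetum gene SHT lay above the 60th percentile on 1 hydrated array each, and 0 of the 9 on both hydrated arrays. The highest signal of any of them on any array was 50.8, for the carpel gene SPT, which lay above the percentile on both tube arrays. Rubisco activase (RCA) read 30.5 and 7.9 in hydrated pollen, with a change of -0.45 against mature pollen (adjusted p = 0.988) and 0.78 in tubes against hydrated pollen (adjusted p = 0.835). The nectary sugar carrier SWEET9 changed by -0.79 (adjusted p = 0.972) and then -0.83 (adjusted p = 0.851). The 3 tapetum markers named were below the filter, and 0 of the 8 epidermis genes were named here.

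The second comparison asked what changes between hydrated pollen and growing tubes. Some transcripts at background in hydrated pollen reached signals above 1000 in tubes. AT3G19940, the hexose transporter STP10, rose at least 58.1-fold to 1525.8 ± 540 (adjusted p = 0.00102), and AT5G09280, of the pectate lyase family, at least 68.8-fold to 1751 ± 114.5 (adjusted p = 0.00658). AT5G11820 rose at least 55.5-fold (adjusted p = 0.000379) and AT5G15560 at least 42.8-fold (adjusted p = 0.000224). AT4G26830, a glycosyl hydrolase of the beta-glucanase type, went from 76.55 ± 12.09 to 2813 ± 285.5 (5.21 ± 0.36, adjusted p = 0.000141). TET8, a tetraspanin of the plasma membrane, rose from 56.7 ± 19.8 to 1567.5 ± 678.3 (4.76 ± 0.46, adjusted p = 0.000394), and AT5G35380, a protein kinase, from 100.75 ± 28.21 to 3735.6 ± 49.71 (5.24 ± 0.62, adjusted p = 0.00127). AT3G15860 rose by 5.11, AT4G21323, a subtilase, by 4.72 and AT1G32920 by 4.48, with adjusted p between 0.0072 and 0.0206.

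Transcripts that fell at this step included abundant ones of both pollen stages. AT4G00350, a MATE-type transporter, went from 5349 ± 1377 to 396.05 ± 255.1 (-3.90 ± 0.44, adjusted p = 0.000963), and AT3G06150 from 5489.7 ± 1836 to 510.85 ± 341.7 (-3.57 ± 0.47, adjusted p = 0.00223). AT1G44000, related to the chlorophyll breakdown factor STAY-GREEN, fell by 3.25 ± 0.31 (adjusted p = 0.000394), the F-box protein AT3G07870 by 3.07 ± 0.44 (adjusted p = 0.00358), the calmodulin-like protein AT1G73630 by 2.91 ± 0.39 (adjusted p = 0.00232) and AT3G10460 by 2.86 ± 0.51 (adjusted p = 0.00994). To background, AT5G43530 was at least 4.74-fold lower in tubes, AT2G16980 at least 4.6-fold, AT5G66290 at least 4.14-fold and AT5G09510, a ribosomal protein of the S15 type, at least 4.05-fold, with adjusted p between 0.00257 and 0.0382.

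**Figure D2:**
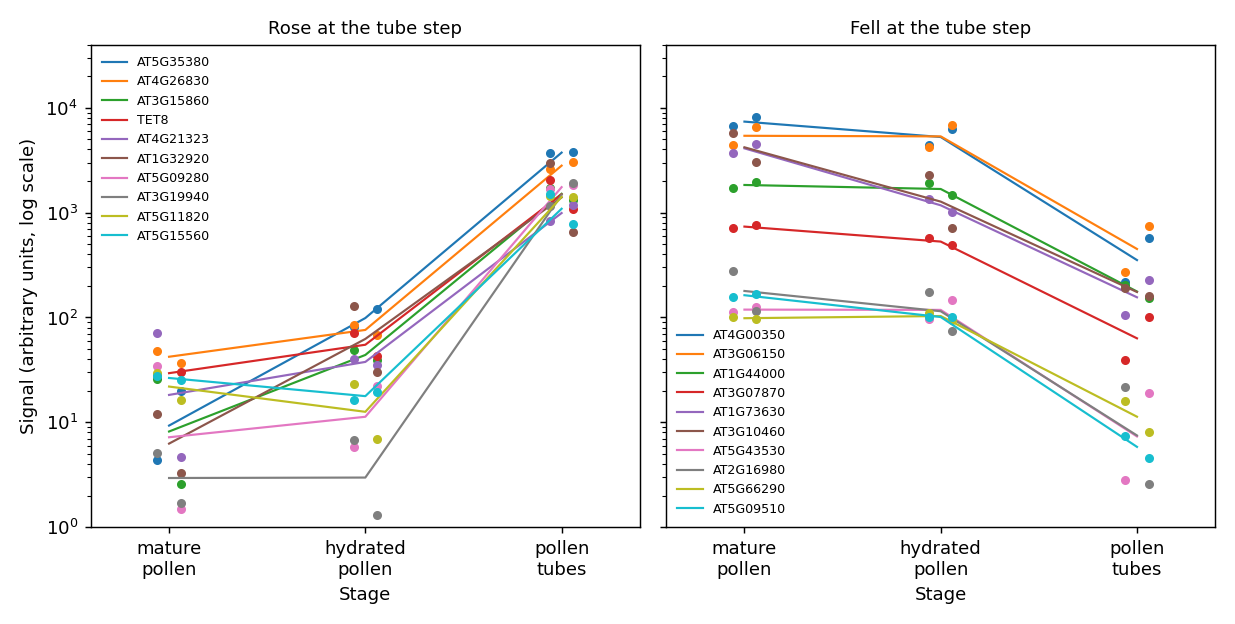
Signal on each array (points, log scale, arbitrary units) by stage for the named genes that rose (left) or fell (right) between hydrated pollen and tubes, with lines through the stage means of log2 signal. AT5G35380 averages 100.75 in hydrated pollen and 3735.6 in tubes, and AT4G00350 averages 5349 and 396.05.

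In all, 522 of the 11412 tested probe sets changed between hydrated pollen and tubes, 290 upward and 232 downward, each by at least 2-fold, and 130 of the rises and 152 of the falls carried 1 gene name. With the replicate number as a block 1646 changed, 775 upward and 871 downward, including all 522. Limma without the intensity trend called 0, with 1494 at an unadjusted p under 0.05. A floor at the 60th percentile gave 221 rises and 37 falls, and scaling to a common 75th percentile 194 and 107. Every array of the compared stages moved the count by over 1.5 times when left out: 109 without tube array 1, 177 without tube array 2, where falls outnumbered rises by 105 to 72, 216 without hydrated array 1 and 235 without hydrated array 2.

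The sugar transport list had 4 tested members, too few for a set test. STP10 rose, SWEET8 rose from 36.25 ± 7.707 to 242 ± 40.59 (2.75 ± 0.59, adjusted p = 0.0254), and the other 2 did not pass. Of 2 calcium and ion transport members, CHX21, a cation exchanger, rose at least 11.2-fold from background (adjusted p = 0.0349). Among 8 actin genes, 1 rose, the actin-bundling fimbrin AT5G55400 (FIM4), from 371.55 ± 72.2 to 1434.8 ± 246.9 (1.95 ± 0.33, adjusted p = 0.0073). Adjusted over the list alone, and with the block, 2 rose and 1 fell, and the list was not called (camera adjusted p = 0.777, median -0.13, mean 0.09). PUB23 rose from 142.55 ± 33.16 to 3191.6 ± 972.9 (4.47 ± 0.73, adjusted p = 0.00642), alone among the 3 touch and wound genes.

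In the cell wall list 0 of 7 members rose, 2 fell and 5 did not pass, with the same counts adjusted over the list alone. Both that fell are pectin methylesterases, enzymes that remove methyl groups from cell wall pectin: AT5G27870 (PME28), from 4532.5 ± 468.1 to 771.65 ± 332 (-2.62 ± 0.45, adjusted p = 0.008), and AT5G07420 (PME49), from 10161 ± 283.8 to 2285.8 ± 278.3 (-2.16 ± 0.32, adjusted p = 0.00377). Camera gave adjusted p = 0.0368 and a median of -0.23, lost at adjusted p = 0.228 with an estimated correlation and at 0.373 after quantile normalization. Pollen transcription factors had 2 falls among 8, AGL29 (-1.72 ± 0.38, adjusted p = 0.0303) and AGL18, from 3927.4 ± 311.8 to 1372.8 ± 239.7 (-1.53 ± 0.29, adjusted p = 0.0128). There were 3 falls adjusted over the list alone and 4 with the block. The median was -0.80 (camera adjusted p = 0.0368, and adjusted p = 0.228 with an estimated correlation). Without hydrated array 2 the adjusted p-values were 0.325 for the cell wall list and 0.11 for the transcription factors, and without tube array 1 they were 0.345 for both. With a floor at the 60th percentile both stood at 0.0761.

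None of the 6 heat shock members passed at the tube step, with AT1G53540 at 1.33 ± 0.47 (adjusted p = 0.176). Adjusted over the list alone 4 rose, as they did with the block. The median was 1.27 and camera called the list upward (adjusted p = 0.00234, and adjusted p = 0.228 with an estimated correlation). Fry gave 0.129 for this list, as for the cell wall list and the transcription factors. Tip growth signalling had 0 of 10 members passing, with 1 rise and 1 fall with the block, and was not called (camera adjusted p = 0.777), with a median of -0.04 and a mean of 0.08. None passed among 4 vesicle traffic genes (PIPK11 -0.37), 2 dehydration and LEA genes (LEA4-5 1.43) and 1 sperm cell gene (MGH3 -0.68, adjusted p = 0.504, and 0.0123 with the block).

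The third comparison set tubes against mature pollen and so summed both steps, along with their differences in collection and handling. AT3G19690 went from 73.8 ± 21.07 to 8399.8 ± 1777 (6.84 ± 0.33, adjusted p = 9.29e-06), AT1G53540 reached 3959 ± 1238 (6.50 ± 0.47, adjusted p = 2.4e-05) and AT4G12980 rose from 54.8 ± 1.556 to 4587.1 ± 315.1 (6.39 ± 0.42, adjusted p = 1.46e-05). From background, AT1G74450 rose at least 140-fold, AT5G35380 at least 128-fold, and PUB23 at least 107-fold. AT1G63060 fell by 4.91 ± 0.31 (adjusted p = 1.35e-05), AT1G73630 by 4.72 ± 0.39 (adjusted p = 5.04e-05) and EXPA24, a cell wall expansin, from 926.95 ± 144.3 to 38.55 ± 14.21 (-4.63 ± 0.42, adjusted p = 8.7e-05). AT2G16980 and AT5G09510 fell to background, at least 7.18-fold and 6.54-fold. In all 901 probe sets changed, 526 upward and 375 downward, each by at least 2-fold, and 2159 with the replicate number as a block, 1127 upward and 1032 downward. Without the intensity trend 228 changed, and with a floor at the 60th percentile 464 rose and 94 fell. The count was 370 without tube array 1 and 442 without tube array 2.

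Of the 6 heat shock members, 5 rose between mature pollen and tubes and 1, AT3G09440, did not pass (2.16, adjusted p = 0.0588). Adjusted over the list alone, and with the block, 6 rose. Hsp70-2 rose at least 30.1-fold, AT5G48570, at background on the second mature array, by 6.20 ± 0.66, and ATHSP22.0 at least 9.17-fold. The median was 5.00, or 4.05 with bounds (camera adjusted p = 1.22e-11, and adjusted p = 0.0952 with an estimated correlation). Pollen transcription factors had 3 falls among 8, all MADS-box genes: AGL18 from 6643.2 ± 164.9 to 1372.8 ± 239.7 (-2.29 ± 0.29, adjusted p = 0.000633), AGL66 (-1.90 ± 0.37, adjusted p = 0.00995) and AGL29 (-1.82 ± 0.38, adjusted p = 0.015). There were 3 adjusted over the list alone and 5 with the block, and the median was -1.17 (camera adjusted p = 0.00138, and adjusted p = 0.138 with an estimated correlation). The list was not called without mature array 2 (adjusted p = 0.0823) or without tube array 1 (adjusted p = 0.0824). AT5G27870 fell by 3.43 ± 0.45 and AT5G07420 by 3.15 ± 0.32 in the cell wall list, which was not called (2 falls also adjusted over the list alone, camera adjusted p = 0.0824) but was called without mature array 1 (adjusted p = 0.00568), without tube array 2 (0.0223) and without a filter (0.0222).

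PUB23 and PUB22 rose among the 3 touch and wound genes, at least 107-fold and 6.88-fold from background (adjusted p = 7.75e-05 and 0.00082). Between mature pollen and tubes STP10 (AT3G19940) rose at least 50.5-fold and CHX21 at least 9.75-fold from background, SWEET8 by 2.68 and the fimbrin AT5G55400 by 2.47. The actin list was not called (1 rise among 8, 2 rises and 2 falls adjusted over the list alone, 2 and 4 with the block, camera adjusted p = 0.739), nor was tip growth signalling (0 of 10 passing, 1 rise and 1 fall with the block, adjusted p = 0.906), whose median of -0.06 was opposite in sign to its test. None passed among the vesicle traffic (PIPK11 -0.39), dehydration and LEA (LEA4-5 0.17), sperm cell (MGH3 -0.77, adjusted p = 0.346, and 0.0039 with the block), photosynthesis (RCA 0.33) and floral organ (SWEET9 -1.62) genes. The F test across the 3 stages called 754 probe sets, 2146 with the replicate block, 62 without the trend, 376 with the floor, 229 without tube array 1 and 312 without tube array 2.

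**Figure D3:**
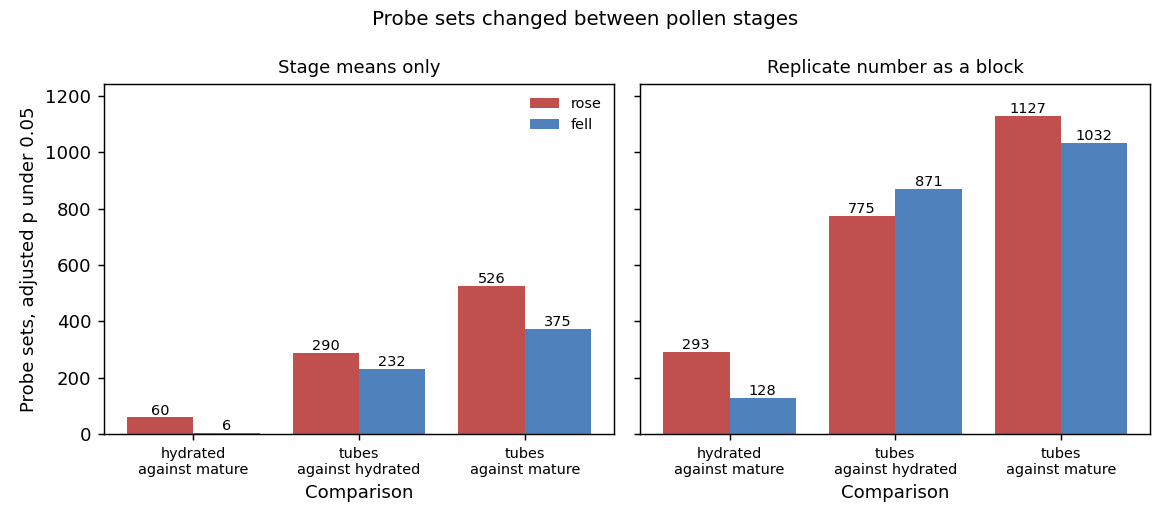
Number of tested probe sets that rose or fell (bars, adjusted p under the threshold) in each comparison, with stage means alone (left) and with the replicate number as a block (right). In hydrated against mature pollen rises exceed falls by 60 to 6 with stage means alone and by 293 to 128 with the block, which raises each count.

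Of the probe sets called at both steps with stage means alone, 14 rose at both steps and 2 fell at both, and 0 changed in opposite directions. The named ones, given after their values were seen, were AT3G19690, AT5G35380, the carboxylesterase CXE18, AT1G67360, of the rubber elongation factor family, and AT3G10300, an EF-hand protein, which rose at both steps, and AT1G63060, which fell at both. Independent lists of these sizes would share 1.65 in the same direction and 1.37 in opposite directions, if every tested probe set were equally likely to be called. Unchanged stages simulated around the same arrays shared a mean of 0 and 0.01. They gave a mean of only 0.02 calls at hydration and 0.01 at the tube step, too few to overlap, so these means are no chance level for the observed counts. The hydrated arrays enter the steps with opposite signs, so their error makes pairs in opposite directions. At an unadjusted p under 0.05, 178 moved the same way and 81 opposite, and the simulated means were 0.23 and 23.8. With the replicate block these counts were 384 and 313, and the simulated means 1.55 and 122. The simulated stages held no change, whereas 705 probe sets at hydration and 1720 at the tube step had an unadjusted p under 0.05 with stage means alone. So these means are no chance level for the observed counts either. At an adjusted p under 0.05 with the block, 175 moved the same way and 41 opposite, where independent lists would share 29.7 and 31.1. The count of 16 fell to 4 without hydrated array 1, hydrated array 2 or tube array 2, and to 3 without tube array 1. Opposite calls numbered 1 without mature array 2, 1 without hydrated array 1 and 2 without hydrated array 2.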

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

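The tests of the replicate-number pattern below were chosen only after the pattern had been seen.

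The difference between the tube step and the hydration step was tested within the same fit. It passed for 21 probe sets, 16 with the higher change at the tube step and 5 with the lower, and 883 had an unadjusted p under 0.05. With the replicate number as a block 703 passed, 292 higher and 411 lower. Of the 21, 7 carried 1 gene name, and they were named after their values were seen. Late rises included AT3G09830, a receptor-like cytoplasmic kinase, whose log2 change at the tube step exceeded that at the hydration step by 6.60 (adjusted p = 0.0189), AT5G15560 (6.51, adjusted p = 0.0208) and AT5G11820 (7.61, adjusted p = 0.0254). For AT4G26830, the beta-glucanase type hydrolase, and AT5G46200 the excess was 4.36 and 4.00 (adjusted p = 0.0254 for both). AT1G74450 went the other way, with most of its rise at hydration (-6.64, adjusted p = 0.0208). So did AT5G37230 (-4.16, adjusted p = 0.0208), with 3.22 at hydration and -0.94 at the tube step. AT1G74450, AT5G11820 and AT5G15560 lay at background in 1 or both pollen stages, so their fitted differences depend on values near background and are no bounds. The difference of AT3G09830 depends on such values too. This gene read 23.3 and 26.1 in hydrated pollen, the first value below its array's 60th percentile and the second little above.

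A control probe set for 25S ribosomal RNA, outside the tests, read higher in replicate 2 of every stage. Its signal was 65 and 427 in mature pollen, 100.4 and 1827.8 in hydrated pollen, and 37.6 and 1241.9 in tubes, log2 differences of 2.72, 4.19 and 5.05. The control probe set for 5S ribosomal RNA read lower in replicate 2 of every stage, at 156.8 and 36.2, 153.7 and 50, and 205.8 and 102.4.

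Arrays sharing a replicate number deviated together in all 3 stages. All 18 of 18 hybridisation control probe sets, added after labelling, were lower in number 2 in every stage. The 18 are not independent, since the controls of an array move together with its scaling. They amount to about 1 outcome over the array pairs of 3 stages, and chance puts such an outcome on 1 side throughout 25% of the time. A batch of labelling or hybridisation that followed the number is a candidate explanation. Array scaling is argued against as the cause of the correlations between replicate differences. On the log2 scale, 1 factor per array shifts all probe sets alike and leaves such correlations as they are. After quantile normalization they were still 0.682 to 0.776 over the probe sets with a mean signal above 200. The controls say less, although 1 factor per array would move them all one way. Of 29 added controls above the 60th percentile on every array, 22 were lower and 3 higher in number 2 in every stage. The 3 were middle parts of the poly-A controls dap and thr. That for thr read 34.8 on the first mature array, where the percentile was 34.1. No biological explanation was tested, so a difference between batches of plants or pollen stays open.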

How the results depend on the processing

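Most alternatives were planned, and the replicate block combined with 2-fold or with quantile normalization, and the added lists, were chosen after seeing the data. In what follows, counts are for hydrated against mature pollen, tubes against hydrated pollen, tubes against mature pollen and, where run, the 3 stages together, reported as 66, 522, 901 and 754. Without a filter, with a filter at the 75th percentile or on mean signal, with quantile normalization, with an offset of 32, with only the 4 arrays compared and with at least 2-fold, these counts stayed within 1.5 times. Of 99 named changes, 97 were kept without a filter, 87 with quantile normalization, 85 with the common 75th percentile and 99 with the offset, and 0 reversed.

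Scaling to a common 75th percentile gave 301 for tubes against hydrated pollen and 641 for tubes against mature pollen, of which 443 rose, and the cause was not tested. It also moved the median log2 change of hydrated against mature pollen from -0.02 to 0.09. A floor at the 60th percentile gave 27, 258, 558 and 376, with falls down from 6 to 0, 232 to 37 and 375 to 94. Limma without the trend gave 0, 0, 228 and 62, with 731 and 1494 at an unadjusted p under 0.05 where 0 passed, and the cause was not tested. An adjusted p under 0.01 gave 40, 235, 468 and 408, as a stricter threshold must give fewer, and 1 probe set per gene gave 37, 284, 469 and 398 with unnamed probe sets left out.

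The replicate block gave 421, 1646, 2159 and 2146, with all 99 named changes kept. The replicate block with at least 2-fold gave 293, 1232 and 1622, and the replicate block with quantile normalization gave 320, 1545, 2068 and 2009. Calls in the same direction at both steps went from 16 to 175 with the replicate block, and were 19 without a filter and 14 with quantile normalization. The block removes the difference between replicate numbers from the residual spread, and false calls in simulation were more frequent with it.

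Leaving out 1 array gave 29 (hydrated 2) to 81 (mature 2) for hydrated against mature pollen, with 38 without hydrated 1 and 43 without either tube array. For tubes against hydrated pollen it gave 109 (tubes 1) to 636 (mature 1), with 177 without tubes 2, 216 without hydrated 1 and 235 without hydrated 2. For tubes against mature pollen it gave 370 (tubes 1) to 767 (hydrated 1), with 442 without tubes 2, and across the stages 229 (tubes 1) to 760 (mature 1), with 312 without tubes 2. Same-direction calls ranged from 3 (tubes 1) to 24 (mature 2), with 4 without hydrated 1, hydrated 2 or tubes 2. Of the 99 named changes 56 were kept without tubes 1, 57 without tubes 2, 70 without either hydrated array, 86 without mature 1 and 93 without mature 2. Fewer arrays leave fewer degrees of freedom.

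Lists called numbered 2, 3 and 2 in the comparisons. Camera with an estimated correlation called 0, 0 and 0 (1, 0 and 1 at an unadjusted p under 0.05). Fry called 1, 0 and 1 (1, 0 and 3 unadjusted). The common 75th percentile gave 1 for hydrated against mature pollen, and the floor gave 1 there and 1 for tubes against hydrated pollen. No filter gave 4 for tubes against mature pollen, where the added lists gave 4 of their own. Leaving out 1 array gave 1 to 3 in each comparison, with 1 without mature 2 or hydrated 1 at the hydration step, without hydrated 2 or tubes 1 at the tube step, and without mature 2 or tubes 1 for tubes against mature pollen. The causes were not tested.

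Signal over background limits the falls, since a transcript near the percentile has little room to fall. In simulation with stage means alone 0% of changes of 1 on the log2 scale were recovered, and with the replicate block 16.2%, 17.3% and 16.6%. A difference between replicate numbers shared by all stages was built into these draws.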

Other observations

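The tests of the heat shock pattern and the counts for the same-direction pattern below were chosen only after those results had been seen. The lists added after the probe annotation had been seen are reported first.

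Among the 19 added lists with enough members, heat shock proteins of the HSP20, HSP70 and HSP90 families were called in every comparison. They share members with the fixed heat shock list, so this is no independent result. Of 12 tested, 4 rose in hydrated against mature pollen (7 adjusted over the list alone): AT1G53540, AT1G54050, Hsp70-2 and AT2G29500, a class I small heat shock protein. The median was 2.90, or 1.43 with bounds, and camera gave adjusted p = 1.27e-11, against adjusted p = 0.109 with an estimated correlation. None of the 12 passed in tubes against hydrated pollen in limma (5 rose with the replicate block), where the list was called at a median of 1.19 (adjusted p = 0.00617, and adjusted p = 0.631 with an estimated correlation). In tubes against mature pollen 7 rose, with a median of 3.46, or 2.56 with bounds (adjusted p = 1.98e-09, and adjusted p = 0.147 with an estimated correlation).

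Tetraspanins, membrane proteins with 7 tested members, were called upward at the tube step (median 1.18, camera adjusted p = 0.00123, and adjusted p = 0.631 with an estimated correlation). TET8, TET16 and TET7 rose, TET16 at least 13.2-fold from background (adjusted p = 0.00917) and TET7 from 118.25 to 401.75 (1.79, adjusted p = 0.0301). There were 4 rises adjusted over the list alone. The list was called again in tubes against mature pollen (3 rises, adjusted p = 0.00184, and adjusted p = 0.603 with an estimated correlation) and not at hydration (0 passing, adjusted p = 0.754). MADS-box factors were called downward in tubes against mature pollen, with 12 of 12 tested members negative and 4 falls, AGL18, AGL21, AGL66 and AGL29 (median -0.65, adjusted p = 0.00615, and adjusted p = 0.561 with an estimated correlation). AGL18, AGL66 and AGL29 are also in the fixed list. At hydration 0 fell and at the tube step 3 (adjusted p = 0.123 and 0.083).

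Ubiquitin-pathway enzymes, with 27 tested members, were called upward at hydration (median 0.30, adjusted p = 0.00551, and adjusted p = 0.508 with an estimated correlation), where PUB49 rose from 38.6 to 320.3 (3.06 ± 0.41, adjusted p = 0.00569). They were not called at the tube step (1 rise, PUB23, adjusted p = 0.994, median -0.19 and mean 0.08) or in tubes against mature pollen (3 rises, PUB23, PUB22 and PUB49, adjusted p = 0.152). Plastid-encoded genes had 0 of 43 passing at hydration in limma, and camera called them (29 of 43 positive, median 0.85, or 0.28 with bounds, adjusted p = 0.00551, and adjusted p = 0.885 with an estimated correlation). They were called again in tubes against mature pollen, with 1 rise, clpP, at least 2.52-fold (adjusted p = 0.0219, and adjusted p = 0.946 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.0514), and not at the tube step (adjusted p = 0.876).

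Several families changed in both directions at the tube step and were not called. Of 25 pectin methylesterases 1 rose, AT5G49180, at least 7.78-fold, and 4 fell: AT5G27870, AT5G07420, AT3G06830 (-2.29) and AT4G15980 (-1.64). In the other comparisons 0 passed at hydration and 4 fell in tubes against mature pollen (camera adjusted p = 0.119 at hydration, 0.441 at the tube step and 0.162 over both). With the replicate block 4 fell at hydration and 5 in tubes against mature pollen. Of 32 polygalacturonases and pectate lyases AT5G09280 rose and AT3G24670 (-2.28) and AT4G33440 (-2.09) fell, with a median of -0.29 and a mean of 0.09 (adjusted p = 0.537). None passed at hydration, and 1 rose and 3 fell over both steps (0.405 and 0.152). Of 11 expansins EXPA16 rose from 129.75 to 1370.1 (3.43, adjusted p = 0.0148) and EXPA24 fell (-2.71, adjusted p = 0.00448). The list gave adjusted p = 0.754, 0.876 and 0.828, with a median of 0.03 and a mean of -0.15 at hydration.

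Single members rose at the tube step in further lists that were not called: SWEET8 of 12 SWEET carriers (adjusted p of the list 0.568, 0.876 and 0.828, in the order of the comparisons), the glycosyltransferase UGT73B5 of 13 (0.119, 0.25 and 0.828; 2.74), and BGLU15 of 7 beta-glucosidases (0.495, 0.341 and 0.828; 1.95). Of 4 CHX exchangers, too few for a set test, CHX19 (2.61) and CHX21 rose. In tubes against mature pollen the tau glutathione transferase GSTU23, of 4 tested, rose (2.50, adjusted p = 0.0339), the ribosomal protein AT1G18540 rose among 74 (1.73, adjusted p = 0.0203; list 0.754, 0.876 and 0.932), and APG8H fell among 9 autophagy genes (-1.84, adjusted p = 0.037; list 0.706, 0.994 and 0.828). None passed in limma in any comparison among 5 RALF-like peptides (0.754, 0.441 and 0.329), 7 trichome birefringence-like proteins (0.754, 0.876 and 0.828), 15 serine carboxypeptidase-like proteins (0.754, 0.745 and 0.828), 14 VPS, SEC and EXO vesicle proteins (0.754, 0.552 and 0.828), 6 IQD proteins (0.754, 0.876 and 0.828), 5 genes with CYP symbols, cytochromes P450 except CYP71, a cyclophilin (0.397, 0.876 and 0.828), 3 xyloglucan endotransglucosylases and 4 glutamate receptor-like channels. In tubes against mature pollen the test was upward where the median was negative for ribosomal proteins (-0.18), glycosyltransferases (-0.44), carboxypeptidases (-0.28) and beta-glucosidases (-0.26), and downward where it was positive for birefringence-like proteins (0.20). At the tube step the median and mean differed in sign for SWEET carriers (-0.05 and 0.08), genes with CYP symbols (-0.19 and 0.09) and autophagy genes (0.15 and -0.03), and the test was upward in each.

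With the replicate number as a block, counts of passing members changed as follows. At hydration 4 pectin methylesterases fell, 2 MADS-box factors fell, 6 heat shock proteins rose, 4 ubiquitin-pathway enzymes rose and 1 fell, 1 expansin rose and 1 fell, and 1 plastid-encoded gene and 1 ribosomal protein rose. At the tube step 5 pectin methylesterases, 4 polygalacturonases and pectate lyases and 4 MADS-box factors fell, 4 tetraspanins, 3 CHX exchangers and 2 glycosyltransferases rose, 3 vesicle proteins rose and 1 fell, 1 autophagy gene rose and 2 fell, 2 ribosomal proteins rose and 1 fell, and 1 ubiquitin-pathway enzyme and 1 tau glutathione transferase fell. In tubes against mature pollen 5 pectin methylesterases and 6 polygalacturonases and pectate lyases fell, 8 heat shock proteins, 4 tetraspanins, 3 plastid-encoded genes and 2 glycosyltransferases rose, 6 ubiquitin-pathway enzymes rose and 2 fell, 4 ribosomal proteins rose and 2 fell, 2 vesicle proteins rose and 1 fell, and 1 autophagy gene rose and 2 fell. There 1 tau glutathione transferase, 1 xyloglucan endotransglucosylase and 1 birefringence-like protein fell as well.

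Among poly-A controls, transcripts added before labelling, 10 of 16 probe sets for the 5' and middle parts were higher in number 2 in all 3 stages and 0 were lower. Most of the 16 read at background on the first mature array, so no ratios are given for them. The middle probe set for dap, above the 60th percentile on every array, read 62.6 and 279.5 in mature pollen, 107.1 and 269.7 in hydrated pollen, and 88.6 and 299.2 in tubes. For the 3' parts 0 of 8 were higher throughout and 4 were lower, with median ratios of 1.01, 0.803 and 0.653.

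Of the 6 tested members of the fixed heat shock list 3 rose in hydrated and 5 in tubes against mature pollen, with the list calls lost at adjusted p = 0.0601 and adjusted p = 0.0952 with an estimated correlation. RNA from other floral tissues is argued against only as far as the named markers reach. Of the 9 named, 0 lay above the 60th percentile on both hydrated arrays and 1, SPT at 50.8 and 25.6, on both tube arrays. Most listed markers were unnamed here, so tissues marked by those stay open. Plastid-encoded genes, which RNA of green tissue would also raise, had 0 of 43 passing at hydration but were called upward (camera adjusted p = 0.00551, and 0.885 with an estimated correlation). Array scaling is argued against, since the lowest median of the list over 3 scalings was 3.66. Collection and incubation in medium cannot be told apart from hydration itself, because mature pollen was never placed in medium, and the median of 1.27 from hydrated pollen to tubes, both shaken and kept in medium, does not separate them. A response to handling and a programme of germination both stay open.

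Probe sets called at both steps with stage means alone moved the same way, 16 to 0. Error of the hydrated arrays, shared by both steps, enters them with opposite signs and so makes opposite pairs. By its sign alone this error would not make same-direction calls, so the counts are no test of it as their cause. At an unadjusted p under 0.05 at both steps, 178 of 259 probe sets moved the same way and 81 opposite. With the replicate block 384 moved the same way and 313 opposite. Opposite pairs exceeded the simulated means of 23.8 and 122, and the cause was not tested. Those means hold replicate error without any change of stage, so they are no chance level for the observed pairs. A difference between replicate numbers leaves every log2 change as it is, because each number holds 1 array per stage, so it was not tested as a cause. It does alter which probe sets were called: with the replicate number as a block, 175 moved the same way and 41 opposite. A gradual change from dry pollen to tubes was not tested either and stays open.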
